A study of Caenorhabditis elegans with 4 samples.

How the data were processed

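The series holds 4 genomic DNA libraries of wild-type *Caenorhabditis elegans* (strain Bristol), prepared from whole animals at the L4 larval stage that had been raised at 22 °C. Per the labels' protocols, animals grew from eggs to L4 with or without antimycin A, an inhibitor of complex III of the mitochondrial respiratory chain, in the agar. For each condition there was 1 library made with an antibody against N6-methyladenine (6mA) and 1 library for which the labels give no antibody. The labels give 1.92 µM antimycin as the treatment of both treated libraries, while the title of the treated antibody library reads 1.93 µM. Methylated DNA immunoprecipitation sequencing (MeDIP-seq) enriches fragments that the antibody binds, and regions where such fragments pile up are called as peaks.

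The deposited table is a single list of annotated peaks for the whole series. Trimmomatic 0.35, Bowtie2 2.2.6, Picard, MACS2 2.1.0 and the genome build ce10 are named, per the submitters' processing notes, without a statement of which step each served. Per the file headers, the table gives for each peak a name, chromosome, start, end, strand, an annotation class, the signed distance to the nearest transcription start, the transcript at that start, and the gene's name, description and type. The tool that made the annotation, the limits of its classes and the rule by which peaks entered the list are not given in the sources used here. The table gives no peak height, fold enrichment, p-value or read count for any peak, so the sequencing depth is unknown and no peak can be ranked by its strength.

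All 365 peak names begin with the same prefix (PO_AA_rep1), which no label spells out. The list was therefore assigned to no library, and no comparison between untreated and antimycin-treated animals was made. The planned overlap of peak sets, change of peak height and stricter peak thresholds need peaks of both conditions or peak scores and were not run. Each condition has 1 library of each kind, so no test between conditions would have had replicates.

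Peak width was computed as end minus start plus 1. Positions are given as deposited, on the build ce10. Shares of peaks carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error over the listed peaks only. Peak counts per nuclear chromosome were compared with each chromosome's share of the summed distance from first to last listed peak, by two-sided exact binomial tests with Benjamini-Hochberg adjustment over 6 chromosomes, since chromosome lengths of ce10 were not used here. No genome or annotation of ce10 was used either, so the annotation classes and the distances to starts were not set against those of random positions. Differences of medians between sets of peaks were tested by two-sided permutation tests with 100000 permutations. All such tests describe where the peaks of this list lie, and peaks are not independent replicates of a condition.

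Gene names and biotypes were checked against an NCBI RefSeq gene table of the assembly WBcel235. Because that assembly differs from ce10, none of its coordinates was used. Of 364 nearest genes, 361 matched a gene of that table by symbol, older name or transcript accession. Of 285 peaks with an annotated transcript, 246 had a transcript that matched.

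Before the data were examined, 23 gene lists were written: mitochondrial, stress, chromatin and tissue marker genes by name, and gene families by symbol. The nearest genes were compared with each list by two-sided Fisher's exact tests against all 46926 genes of the table, with Benjamini-Hochberg adjustment. Protein-coding genes (19983) as background, and 10000 random gene sets matched on length in 10 bins, were set as other backgrounds beforehand. The list of genes of the mitochondrial DNA could not be tested, because its symbols do not occur in the gene table, which leaves 22 tests. In the other lists 3 names did not match. The rule for genes named in the text was also fixed then: members of the mitochondrial, antioxidant and chromatin lists with a peak, and 4 members of any other list past an adjusted p of 0.05. Its parts that rank peaks by height could not be applied. The 10 widest peaks and the other single genes named below were chosen after their values were seen.

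The list tests and the chromosome test were tested on simulated data. The chemoreceptor list (1628 genes, 12.5 expected by chance), drawn at 3 times its chance, was called in 100 of 100 simulated gene sets, with 5 calls among 2100 tests of the other lists. No other list was simulated this way, including those that expect under 1 gene. Chromosome X at 2 times its share was called in 100 of 100 sets, and 3 of 100 unchanged sets gave any call. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1 were used.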

Results

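Genomic DNA of whole L4 *C. elegans* was profiled by 6mA MeDIP-seq to ask how N6-methyladenine in the genome changes when mitochondrial respiration is inhibited by antimycin A. There were 4 groups of 1 library each: an antibody and a no-antibody library of untreated animals, and the same pair from antimycin-treated animals. The data consisted of 1 list of 365 peaks with the authors' annotation and without peak heights or read counts. The list could not be tied to a library by its labels, so the results describe where these peaks lay, and a contrast of treated with untreated animals was not analysed here.

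Peaks lay on all 6 nuclear chromosomes and on the mitochondrial genome. The 364 nuclear peaks had a median width of 404 bp (quartiles 310 and 542 bp, range 229 to 1732 bp) and covered 169879 bp together. The single mitochondrial peak ran from position 22 to 3998 of the mitochondrial genome. Its 3977 bp made it the widest peak of the list, 2.3 times the widest nuclear one, and the table names no gene for it. The widest nuclear peak (chromosome X, 9186994 to 9188725) lay in intron 3 of 4 of a transcript assigned to Y81B9A.2. The next were an intergenic peak of 1638 bp nearest to *ddl-3* (chromosome II, 14337685 to 14339322) and one of 1602 bp nearest to *efhc-1*, which encodes an EF-hand protein (chromosome X, 10361092 to 10362693). F58A6.1 (1421 bp), the piRNA gene 21ur-8623 (1362 bp), Y70D2A.6 (1312 bp), the metalloendopeptidase gene *nas-6* (1297 bp), F46F2.12 (1186 bp) and *isp-1* (1170 bp) completed the 10 widest.

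**Figure D1:**
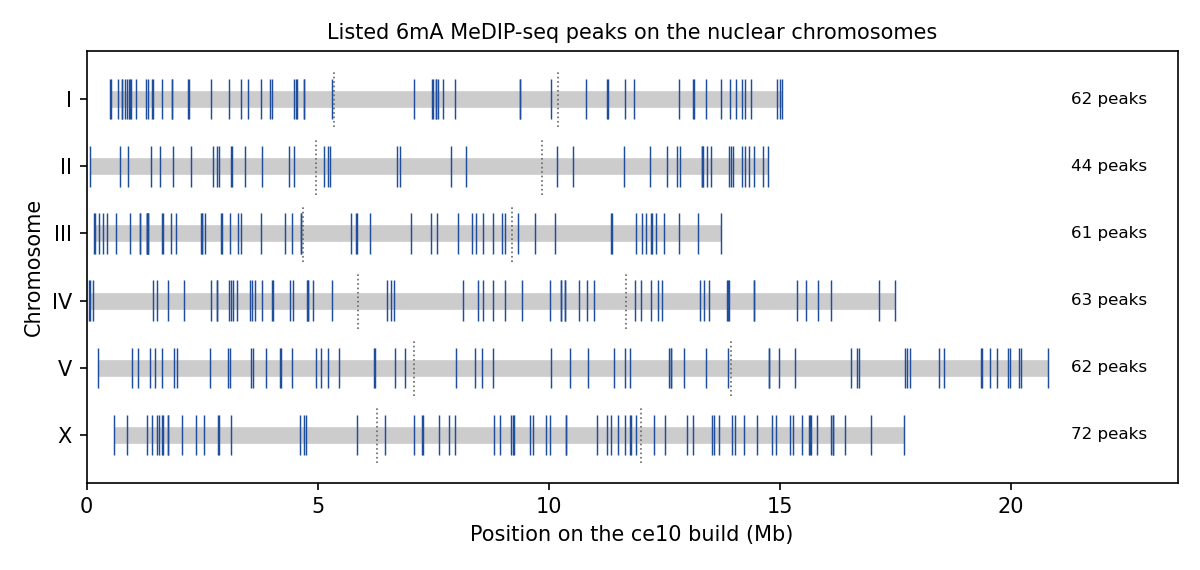
Position of each listed peak (blue line) on the 6 nuclear chromosomes, in Mb of the ce10 build; the grey bar runs from the first to the last listed peak and dotted lines divide it into 3 equal parts. Chromosome X held 72 peaks and chromosome II 44, and the middle parts of chromosomes I and II held 11 and 7.

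Chromosome X carried 72 peaks and chromosome II 44, with 61 to 63 on each of the others. Per Mb of the distance between first and last peak, chromosome III had 4.50 peaks (95% Poisson interval 3.44 to 5.78), chromosome I 4.26 (3.27 to 5.46) and chromosome X 4.21 (3.30 to 5.30). Chromosome IV had 3.61 (2.78 to 4.62), chromosome V 3.02 (2.31 to 3.87) and chromosome II 2.997 (2.18 to 4.02). No chromosome's count differed from its share of that distance. In 6 exact binomial tests the lowest adjusted p was 0.247 and 0 had an unadjusted p under 0.05. The 261 peaks nearest to protein-coding genes were also set against the number of protein-coding genes, a base chosen after the data were seen, and 0 chromosomes passed (lowest adjusted p = 0.051, exact binomial tests). Chromosomes I, II, III and V shared that adjusted p, with unadjusted p of 0.0219 to 0.034 (exact binomial tests). Chromosomes I and III had more of these peaks than expected (50 against 37.6 and 47 against 34.53). Chromosomes II and V had fewer (32 against 45.04 and 49 against 65.28). Chromosome IV had 44 where 42.88 were expected. Chromosome X had 39 of these peaks where 35.7 were expected (unadjusted p = 0.529, exact binomial test). Its other 33 peaks were nearest to genes of other types.

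The largest annotation class was promoters, with 138 of 365 peaks (37.8%, 95% interval 32.8 to 43.0%). The share of the genome in each class was not available here, so these shares do not show enrichment. Among these were peaks 226 bp upstream of the start of *daf-19*, which encodes an RFX transcription factor of ciliated neurons, and 59 bp upstream of *daf-1*, which encodes a TGF-beta type receptor of the dauer pathway. Others lay 302 bp upstream of *mff-1*, a mitochondrial fission factor gene (chromosome X, 12987386 to 12987624), and 217 bp upstream of *aco-1*, which encodes the cytoplasmic aconitase (chromosome X, 11339465 to 11339854). Further promoter peaks lay 417 bp upstream of the microRNA Argonaute gene *alg-1*, 287 bp upstream of *kin-1*, which encodes the catalytic subunit of protein kinase A, and 549 bp upstream of the MAP kinase kinase kinase gene *mlk-1*. The promoter peak nearest to *hlh-30*, which encodes a TFEB-like regulator of autophagy genes, lay 136 bp upstream of its start (chromosome IV, 4027978 to 4028466). The table ties that peak to the transcript of another gene, F35F11.4.

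Intergenic peaks numbered 79 (21.6%, 17.5 to 26.2%) and intronic peaks 75 (20.5%, 16.5 to 25.1%). Intronic peaks included one of 1066 bp in intron 5 of 9 of *polg-1*, the gene of the mitochondrial DNA polymerase gamma (chromosome II, 12194405 to 12195470). They also included one in intron 1 of 7 of *egl-30*, which encodes a Gq alpha subunit, and one in intron 6 of 10 of *lonp-2*, which the table describes as a peroxisomal Lon protease. Intron 2 of 18 of *unc-43*, the gene of calcium/calmodulin-dependent kinase II, held 2 peaks. A further 57 peaks (15.6%, 12.1 to 19.7%) were assigned to transcription termination sites. Exons held 13 peaks (3.56%, 1.91 to 6.01%), among them exon 2 of 9 of the chromodomain helicase gene *chd-7* and exon 2 of 7 of the chitinase gene *cht-4*, and 2 peaks lay in non-coding transcripts.

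**Figure D2:**
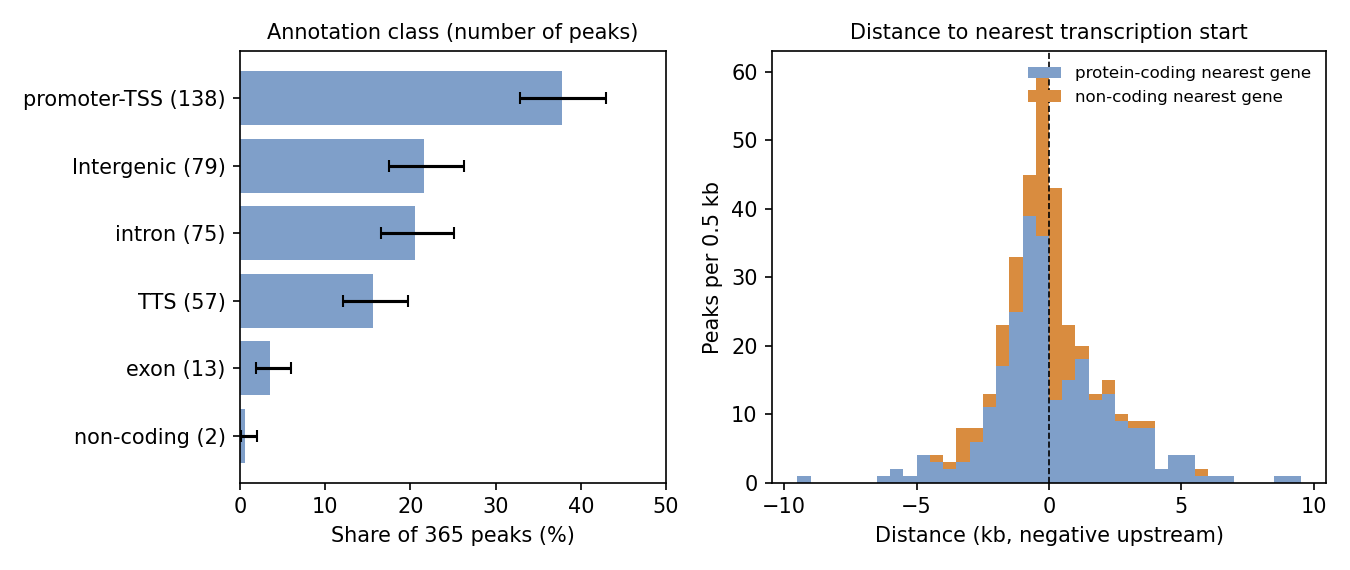
Left, share of the 365 peaks in each annotation class (%), with exact 95% binomial intervals as bars and the number of peaks in brackets; 1 mitochondrial peak has no class. Right, stacked histogram of the distance from 364 peaks to the nearest transcription start (kb, negative upstream), split by type of nearest gene; 206 peaks lay upstream and 158 downstream.

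Peaks lay a median of 1104.5 bp from the nearest transcription start, on either side (quartiles 415 and 2180 bp), and the distance that random positions would have was not computed. Of 364 peaks, 171 (46.98%, 41.8 to 52.3%) were within 1000 bp of a start and 15 (4.12%, 2.32 to 6.71%) beyond 5000 bp. The peaks farthest from a start included one nearest to the aldehyde dehydrogenase gene *alh-12*, 9195 bp upstream, and one nearest to Y54F10AL.1, 9349 bp downstream. More peaks lay upstream of the nearest start (206) than downstream (158; two-sided exact binomial p = 0.0137 against equal numbers, which random positions need not give).

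Protein-coding genes were nearest to 261 peaks (71.7%, 66.8 to 76.3%) and ncRNA genes to 102 (28.0%, 23.5 to 32.9%), and the remaining peak, 5 bp upstream of the microRNA gene *mir-73*, has the type miscRNA. A further microRNA gene, *mir-2215*, is typed as ncRNA, and its peak lay 1576 bp upstream of its start. Peaks nearest to ncRNA genes lay closer to the start, at a median of 437 bp against 1325 bp for protein-coding genes (difference 888 bp, permutation p = 1e-05, the smallest the test can give). They were also annotated as promoter more often, in 54.9% (44.7 to 64.8%) against 31.03% (25.5 to 37.0%) of peaks (Fisher's exact p = 3.75e-05). Both comparisons reflect nearness to a start and are not separate results. Gene length was not taken into account in either. The gene named as nearest was not always the one that the peak was annotated to. In 69 of 246 peaks that could be compared (28.0%, 22.5 to 34.1%), the gene table gave the annotated transcript to another gene. For instance, the peak nearest to *ced-1*, an engulfment receptor gene, lay in intron 5 of 9 of *dhhc-2*, 6177 bp from the start of *ced-1*. The peak nearest to *crn-1*, a flap endonuclease gene, lay in intron 14 of 22 of *ccep-290*. The 69 also include the peak nearest to *unc-60*, whose annotated transcript was the one at the nearest start. There only the gene names differ, because the gene table gives that transcript to F53E2.2.

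Genes of the respiratory chain were represented by 1 of the 49 list members, *isp-1*, which encodes the Rieske iron-sulphur subunit of complex III. Its peak (chromosome IV, 8134872 to 8136041, 1170 bp) was centred 584 bp downstream of the *isp-1* start and was annotated as the promoter of the non-coding gene F42G8.16. No member of the mitochondrial unfolded protein response list (28 genes, including the chaperone genes *hsp-6* and *hsp-60* and the regulator *atfs-1*) was nearest to a listed peak. No member was found in the list of 6mA and histone modifying enzymes either (30 genes, including *damt-1* and *nmad-1*). That list does not hold every *set-* gene: *set-15*, outside it, was nearest to a listed peak 1219 bp upstream of its start (chromosome IV, 4781106 to 4781499). Of 38 antioxidant and detoxification genes, only *wdr-23*, which encodes a negative regulator of the stress factor SKN-1, had a listed peak, 873 bp upstream of its start (chromosome I, 7595532 to 7595774). Chance gave 0.215, 0.231, 0.377 and 0.292 genes in the unfolded protein response, enzyme, respiratory chain and antioxidant lists, so these counts could not have shown fewer genes than chance, and the Fisher's exact tests found no excess (adjusted p = 1.0, 1.0, 0.991 and 0.991).

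Among tissue markers, 1 of 30 neuronal genes, the neurexin gene *nrx-1*, had a peak, 409 bp upstream of its start. None of the 25 muscle, 30 germline or 24 intestinal genes had one, and none of these 4 lists passed Fisher's exact test (adjusted p = 0.991 for the neuronal genes and 1.0 for the others). Chance gave 0.192 muscle, 0.231 germline, 0.185 intestinal and 0.231 neuronal genes, so these counts could not have shown fewer genes than chance either. Among gene families, 10 of 1628 chemoreceptor genes had a listed peak (12.5 expected, adjusted p = 1.0, Fisher's exact test), among them *srg-36*, *sre-47* and *srh-19*. Of 264 C-type lectin genes 5 had one (2.03 expected), namely *clec-9*, *clec-80*, *clec-112*, *clec-113* and *clec-185* (Fisher's exact p = 0.0543, adjusted p = 0.597). The nuclear hormone receptor genes *nhr-237*, *nhr-239* and *nhr-247* made 3 of 283 (2.18 expected), and *fbxa-15*, *fbxa-55* and *fbxa-75* made 3 of 391 F-box genes (3.01 expected). The ABC transporter gene *haf-7* and the major sperm protein gene *msp-113* were the single members of their families. The collagen list took all symbols beginning *col-*, *dpy-*, *rol-*, *sqt-* or *bli-*, whatever the product (197 genes). It had none, where chance gave 1.52 (Fisher's exact p = 0.412). Histones (72), cytochromes P450 (80), UDP-glucuronosyltransferases (67), glutathione S-transferases (44), ribosomal proteins (78) and ribosomal RNA genes (21) had none either. Chance gave 0.162 to 0.615 genes of each of these.

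The piRNA genes were nearest to 14 peaks, of which 12 lay on chromosome IV, where the gene table places 14714 of its 15363 piRNA genes. The 4 widest were those nearest to 21ur-8623 (1362 bp), 21ur-12944 (941 bp), 21ur-5666 (783 bp) and 21ur-1709 (749 bp). By their number among all genes, 118 piRNA genes were expected, and this was the single list of 22 past the threshold. This outcome followed from the base of all genes. Chromosome IV held 42.02% of those genes but 17.3% of the nuclear peaks, which is near its 17.8% share of the summed peak span. If each of its 63 peaks were nearest to a piRNA gene, the count would be 65 and still pass as fewer (Fisher's exact p = 4.07e-10). The test against all genes therefore does not show that peaks avoid piRNA genes. On chromosome IV alone, piRNA genes were nearest to 19.05% of peaks (95% interval 10.25 to 30.9%) and made up 74.7% of the genes in the table, a share by number that takes no account of how much sequence lies nearest to each gene, which was not tested. Against random genes of matched length, 21.2 were expected and the count did not pass (adjusted p = 0.0968, permutation test). Those sets keep the observed number of genes in each length bin. A shortage of genes as short as piRNA genes is thus built into the 21.2, and the match cannot weigh it. None of the other 21 lists passed Fisher's exact test against all genes, and 0 of them had an unadjusted p under 0.05.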

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

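Merging peaks within 1000 bp left 364 of 365 peaks. Counting base pairs instead of peaks left 0 chromosomes past the threshold, as before, while 3 chromosomes passed with protein-coding gene numbers as the base and 4 with the numbers of all genes, of which chromosome IV carries 42.02%. The former base is mismatched, because peaks nearest to other genes were counted too. With only peaks nearest to protein-coding genes, 0 passed. Of the chromosomes called on the former base (II, V and X), only chromosome X then came near its expectation. Chromosomes II and V still had fewer peaks than expected, at an adjusted p of 0.051 (exact binomial tests). The mismatch therefore cannot be taken as the reason for the calls on chromosomes II and V. These gene-number bases were chosen after seeing the data. The share of promoter peaks, 37.8% by the deposited classes, was 21.4% when a promoter was taken as 500 bp upstream to 100 bp downstream of the nearest start, 33.8% with 1000 bp upstream (added after seeing the data) and 49.2% with 2000 bp upstream. The wider window takes in more peaks by its construction. The single gene list past the threshold, the piRNA genes, became 0 lists with length-matched gene sets, with protein-coding genes as background and, added after seeing the data, with a background without piRNA genes. The last 2 backgrounds hold no piRNA gene, and none of the other 21 lists passed under any of the 3 settings that could test it. With length matching the ratio of observed to expected piRNA genes moved from 0.119 to 0.66. Because the match keeps the observed number of genes in each length bin, this move is no independent sign of a weaker deficit. Stricter peak thresholds, the overlap rules for 2 peak sets and the rescaled peak height were not run, because the table lists neither scores nor a second peak set. No paired analysis was possible because each group has 1 library and the list belongs to no named library. Depth is unknown, so a gene without a listed peak cannot be called free of 6mA.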

Other observations

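The tests of the autosomal share outside the middle, of uniform spacing and of first introns were set up before their results were seen. The comparison of chromosome X with the autosomes, the shifted placements, the leaving out of single-intron transcripts and the tests on peak numbering, repeated genes, the mitochondrial peak and peak width were chosen after.

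Of the listed neighbours on the nuclear chromosomes, 29 pairs had centres within 10 kb of each other. The family members *pals-11* and *pals-7* each had an intronic peak (chromosome I, 13124862 to 13129760, centres 4261 bp apart). A run of 5 peaks on chromosome III (1299667 to 1327391) was nearest to *anr-53*, *fbxa-75*, Y82E9BL.12, *fbxa-15* and *linc-40*. The peak nearest to *anr-53* was annotated to the termination site of a further F-box gene, *fbxa-28*. Intron 2 of *unc-43* held peaks 2538 bp apart, one of which was assigned to the piRNA gene 21ur-14024, and the peak nearest to Y71H10B.1 was annotated to the kinase gene *kin-29*, whose own promoter also carried a peak. Uniform placement within chromosomes gave 13.2 such pairs (95% range 7 to 21, permutation p = 0.001, the smallest that 1000 placements can give). Shifting each peak by up to 250 kb, which keeps the broad pattern along the chromosome, gave 14.8 (8 to 22, permutation p = 0.001). Listed peaks thus lay closer together than either placement gave. Of the 29 pairs, 27 had consecutive peak numbers. The positions of the numbered peaks that are not listed are unknown, so close spacing of all numbered peaks could not be told from close spacing of this list. Repeats, mappability and gene content were not tested here either.

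Autosomal peaks lay more often toward the chromosome ends. Of 282 autosomal peaks, leaving out the first and last of each chromosome, 217 (76.95%, 95% interval 71.6 to 81.7%) lay outside the middle one of 3 equal parts of the peak span, where even placement gives 66.7% (two-sided exact binomial p = 0.000185). The tests and intervals here treat peaks as independent, whereas listed peaks lay closer together than uniform placement gave. The p may therefore be too low and the interval too narrow. The share was highest on chromosome II (83.3%) and lowest on chromosome IV (72.1%). On chromosome X it was 62.9% (50.5 to 74.1%, n = 70), lower than on the autosomes (Fisher's exact p = 0.0217). The numbering does not show that contrast: 69.7 to 72.9% of the numbers on chromosome X lay there, which is within the range for the autosomes given next, and listed against other numbers on X gave a Fisher's exact p of 0.0469 to 0.185. One explanation is that the listed peaks only follow all numbered peaks. Depending on where the borders fall between listed peaks, 65.6 to 75.5% of the 1288 autosomal numbers lay there, and the Fisher's exact p was 0.532 at the border most favourable to that explanation and 3.81e-06 at the other. Interpolating the numbers between listed peaks put 68.9% of them there (Fisher's exact p = 0.000809), with 66.1 to 71.1% on single autosomes, below the listed share on each of the 5. Because the actual positions of the other numbers are unknown, the explanation stays open for the autosomes, as does a selection of the listed peaks by position. Repeats and mappability, which could also differ between the arms and centres of autosomes, were not tested, because no sequence of ce10 was used here. Gene content, as a biological explanation, was not tested either.

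The peak numbers rise with position on every chromosome and reach 1645, so the 365 listed peaks are 22.2% of the numbers up to the highest, and the other numbers are not analysed here. Per chromosome, 19.05 to 24.9% of the numbers were listed, and no difference between the 6 nuclear chromosomes was detected (permutation p = 0.774). A total of 88 neighbours had consecutive numbers, where random draws gave 80.5 (95% range 66 to 95). The 364 nearest genes are all different. Of 147 peaks within a gene or at a termination site, 3 repeated a transcript that another such peak had. A repeated transcript need not mean the same gene copy. Peaks given intron 1 of 1 of Y67D8A.8 start at 15806470 and at 16098006 on chromosome X, and whether that intron spans both was not checked. Whether the list was reduced to 1 peak per nearest gene stays open, because the absence of repeats prompted the question and no independent value in the table bears on it. No biological explanation was tested for the numbering.

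The mitochondrial peak is hard to weigh. The many copies of mitochondrial DNA per cell could raise its coverage without any 6mA, but the table lists no coverage in the antibody or no-antibody libraries, so this and methylation of mitochondrial DNA cannot be told apart from a width of 3977 bp. No biological explanation was tested.

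Intronic peaks were wider than promoter peaks, with medians of 518 and 376.5 bp (difference 141.5 bp, permutation p = 1e-05, the smallest the test can give). The other classes were not tested. Their medians were 401 bp (intergenic), 360 bp (termination sites), 368 bp (exons) and 496 bp (the 2 peaks in non-coding transcripts), so intronic peaks had the largest median of all classes. Intronic peaks showed no measurable preference for the first intron when every intron had an equal chance. Leaving out 7 of the 75 that lay in transcripts with a single intron, 13 of 68 lay in the first, where 12.2 were expected (one-sided exact Poisson-binomial p = 0.452). Intron length was not taken into account, so 12.2 need not be what random positions within introns would give.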
